A study of Drosophila melanogaster with 42 samples.

How the data were processed

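The series holds 42 ChIP-seq samples of Drosophila melanogaster embryos at 3-4 h and 11-12 h, 26 of ChIP and 16 of input. MSL2, MOF and H4K16ac were measured on MNase-digested chromatin in 3 samples per stage, and H4K16ac and H3K36me3 on sonicated chromatin in 2 samples per stage. Samples were grouped by antibody, chromatin preparation and stage from their titles. The files used were 12 peak lists deposited by the authors, each a list of chromosome, start and end with no score, height, strand or read count. The sample descriptions name 1 list for all replicates of a group, so no value per replicate was at hand and the depth per sample is unknown. The submitters' processing notes name Bowtie2 2.2.9, SAMtools, HOMER and the genome build dm6, without the role or settings of each tool; the peak calling settings and how replicates or inputs entered the lists are not given in the sources used here. The subnucleosomal MSL2 lists hold regions of 200 bp only, and the narrowest region of the other lists is 1000 bp, or 2000 bp for MSL2 mononucleosomal fragments.

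Regions were counted on the arms X, 2L, 2R, 3L and 3R, and regions elsewhere were counted apart. Genes came from a table of RefSeq genes on the Release 6 assembly, the same assembly as dm6, of which 13842 protein-coding genes lie on these arms. The length of an arm was taken as the last position of a gene or region on it, since no genome sequence was used here. A region was named by the gene whose body it overlaps most, else by the nearest gene. The rule for named genes, set before the data were examined, took all members of 9 fixed gene lists as counts with examples, the genes at the 10 widest X regions of each MSL2 mononucleosomal and MOF list, and the genes at the 8 widest X regions of H4K16ac and H3K36me3 in both stages, at 3-4 h only and at 11-12 h only. The highest score was to be used where a list had one, and width took its place; the subnucleosomal peaks share 1 width and were not ranked. The MSL2 sites in all 4 lists and the autosomal regions named in the closing section fall outside that rule and were chosen after their values were seen.

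Two-sided Fisher's exact tests compared the X share of regions between stages, the kept share between X and autosomes, the overlap between lists between stages, the genes touched, the midpoints in gene bodies, the fixed lists and the number of H4K16ac regions by stage and preparation. The tests of genes between stages treat the same genes at both stages as independent, and gained and lost genes are given beside them. Overlap of at least 1 bp was compared with 10000 circular shifts of the regions along each arm, one-sided, with 1000 shifts for alternatives. Differences of median width and of median distance were tested by two-sided permutation with 100000 resamples, or by exact enumeration where there were no more splits than that. Shares have Wilson intervals, differences of shares Newcombe intervals, and ratios of covered length intervals from 10000 bootstrap draws of 1-Mb blocks, all at 95%. P values were adjusted by Benjamini-Hochberg within each family, with 0.05 as the threshold. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

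The code was tested on simulated data. Overlaps and covered lengths matched a count base by base in 20 of 20 simulations. The placement test called 7 of 200 pairs of unrelated clustered lists, 18 of 200 when 10% of the arm was empty in both lists, and 200 of 200 when 20% of the regions were planted. The test of the X share called 7 of 200 with no change and 200 of 200 with a change of 10 points, with the interval holding the planted change in 193 of 200. The median test called 14 of 200 with no change and 200 of 200 with a 1.5-fold change. The simulations of the X share and the median drew independent values. They check the code only, since regions of the real lists cluster and are largely shared between stages.

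Alternatives were the widest 50% of each list, regions within 1 kb joined, covered length in place of regions, every sequence of a list, overlap of at least 50% of the shorter region, a gap of 1 kb allowed, placement inside gene bodies, at least 50% of the gene body, 1 kb added to genes, other MSL2 lists as sites, midpoint distance and any base in a gene. For the preparations, X-linked regions only, autosomal regions only, the widest 50% of both stages and joined regions were added after the data were seen, and so were the same number of widest regions from both lists for the X share and the width classes for H4K16ac at gene ends. Left out from the plan were GA repeats in MSL2 peaks, which need a genome sequence not used here, and promoter, UTR, exon and intron classes with their wider promoter, since the gene table has neither strand nor exons. Placement in gene bodies was tested in their place. A replicate block and the lists without each replicate in turn could not be computed from lists that pool the replicates.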

Results

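Drosophila melanogaster embryos of 3-4 h and of 11-12 h were studied by chromatin immunoprecipitation and sequencing (ChIP-seq) in 42 samples, 26 of ChIP and 16 of input. On chromatin digested with micrococcal nuclease (MNase), MSL2, MOF and histone H4 acetylated at lysine 16 (H4K16ac) were each measured in 3 samples per stage, with 6 inputs per stage. On sonicated chromatin, H4K16ac and histone H3 trimethylated at lysine 36 (H3K36me3) were each measured in 2 samples per stage, with 2 inputs per stage. MSL2 is the male-specific subunit of the dosage compensation complex, MOF is its acetyltransferase for H4K16, and H3K36me3 marks the bodies of transcribed genes. The values used here were 12 deposited lists of regions, 1 per antibody, preparation and stage, with separate MSL2 lists for mononucleosomal and for subnucleosomal fragments. The MOF and MNase H4K16ac lists are named as mononucleosomal too, and have no subnucleosomal counterpart here. Each list stands for all replicates together, so no value has a replicate error or an SD, and tests compare lists over regions, which are not replicates. By their titles, MSL2 samples are replicates A to C, MOF and MNase H4K16ac samples D to F, and sonicated samples A and B. The lists carry no score and no read count, so the depth is unknown. Values in brackets are 95% intervals that cover counting error over regions, genes or blocks of the genome only. MNase was used at 0.9 units per g at 3-4 h and at 2.9 units per g at 11-12 h, so digestion and stage changed together in the MNase lists. Positions are on dm6, counted from 1; autosomes means the arms 2L, 2R, 3L and 3R.

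The first comparison asked how far each signal was confined to the X chromosome at the 2 stages. MSL2 mononucleosomal regions lay almost wholly on the X at both, 238 of 245 (97.1%, 94.2 to 98.6) at 3-4 h and 310 of 318 (97.5%, 95.1 to 98.7) at 11-12 h. MSL2 subnucleosomal peaks were also mostly X-linked at 3-4 h, 116 of 130 (89.2%), but at 11-12 h only 167 of 295 (56.6%) were, with 14 and 128 autosomal peaks at the 2 stages. MOF regions on the X numbered 475 of 515 (92.2%) and then 526 of 608 (86.5%), with 40 and 82 autosomal regions. The widest MSL2 mononucleosomal region of 3-4 h, 16.8 kb at X 3948557 to 3965384, lay mostly over lva, a Golgi-associated protein, and the others among the 10 widest lay over PhKgamma, tay, pcx, RhoGAPp190, Tao, Rok, tty, Ubr1 and CG34408. At 11-12 h the widest, 9.78 kb at X 19482360 to 19492136, lay over pcm, an exoribonuclease, followed by dlg1, RhoGAPp190, crm, PhKgamma, CG34408, RhoGAP16F, Nup153, Usp2 and tay. The widest MOF region of 3-4 h, 42.3 kb at X 15713136 to 15755401, spanned the ubiquitin ligase gene HUWE1, and that of 11-12 h, 38.3 kb at X 6804793 to 6843135, spanned nonC, a kinase of nonsense-mediated decay. Other wide MOF regions lay over bif, CG2186, Rbcn-3A, mxc, Top1, Elys, bbx and e(y)3 at 3-4 h, and over HUWE1, Top1, CG2186, Spg7, pcx, mxc, Polr2A, ebo and e(y)3 at 11-12 h. By Fisher's exact test, two-sided and adjusted over the 6 list pairs, the X share of MSL2 subnucleosomal peaks changed by -32.6 points (-39.7 to -24.1, adjusted p = 1.35e-11). By the same exact test the MOF share changed by -5.72 points (-9.29 to -2.10, adjusted p = 0.0031), and MSL2 mononucleosomal regions differed by 0.341 points (-2.45 to 3.51, adjusted p = 0.862). The MOF change turned to 1.22 points when the widest 50% of each list was compared, -0.0303 points when the same number of widest regions was taken from both lists, and -0.881 points when covered length was counted.

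H4K16ac on the X grew in length between the stages in both preparations, whereas the length under H3K36me3 was nearly the same. On MNase chromatin the regions covered 3.92 Mb of the X at 3-4 h and 7.70 Mb at 11-12 h, 1.96 times as much (1.85 to 2.09), or 16.7% and 32.7% of the chromosome. On sonicated chromatin they covered 3.70 and 5.34 Mb of the X, a ratio of 1.45 (1.40 to 1.49). The autosomes went different ways in the preparations: covered length fell from 4.33 to 2.50 Mb on sonicated chromatin (ratio 0.578, 0.556 to 0.600) and rose from 1.01 to 1.74 Mb on MNase chromatin (ratio 1.72, 1.57 to 1.90). H3K36me3 covered 3.22 and 3.29 Mb of the X (ratio 1.02, 0.9995 to 1.045) and 14.2 and 14.3 Mb of the autosomes (ratio 1.01). The MOF length on the X rose 1.11 times (1.08 to 1.13) and that of MSL2 mononucleosomal regions 1.10 times (1.02 to 1.18). Counted as regions and tested by the same exact test, the X share of sonicated H4K16ac rose from 28.2% to 38.2% (9.99 points, 7.41 to 12.6, adjusted p = 2.29e-13), and that of MNase H4K16ac fell from 57.2% to 45.6% (-11.6 points, -15.0 to -8.22, adjusted p = 4.71e-11). The H3K36me3 share was 19.2% and 19.3% (exact test, adjusted p = 0.862), against 17.8% for the X share of the length of the 5 arms and 15.9% for its share of their protein-coding genes. Counted as covered length, the MNase change turned to 2.10 points, from 79.5% to 81.6%, and the sonicated change grew to 22.05 points, from 46.0% to 68.1%.

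**Figure D1:**
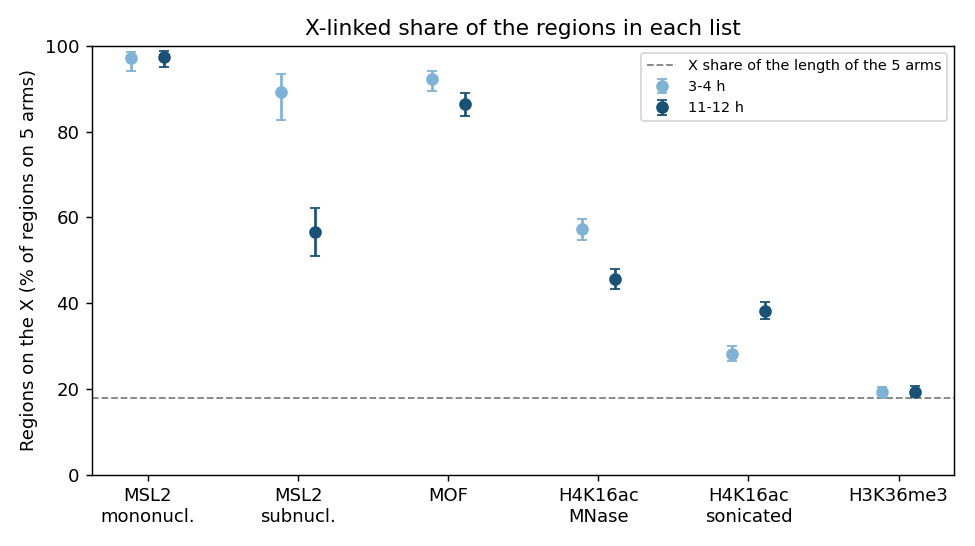
X-linked share of the regions on the 5 arms for each antibody and preparation at 3-4 h (light) and 11-12 h (dark), in percent, with Wilson 95% intervals over regions; the dashed line is the X share of arm length, 17.8%. MSL2 mononucleosomal regions stay near 97% at both stages, while MSL2 subnucleosomal peaks go from 89.2% to 56.6%.

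**Figure D2:**
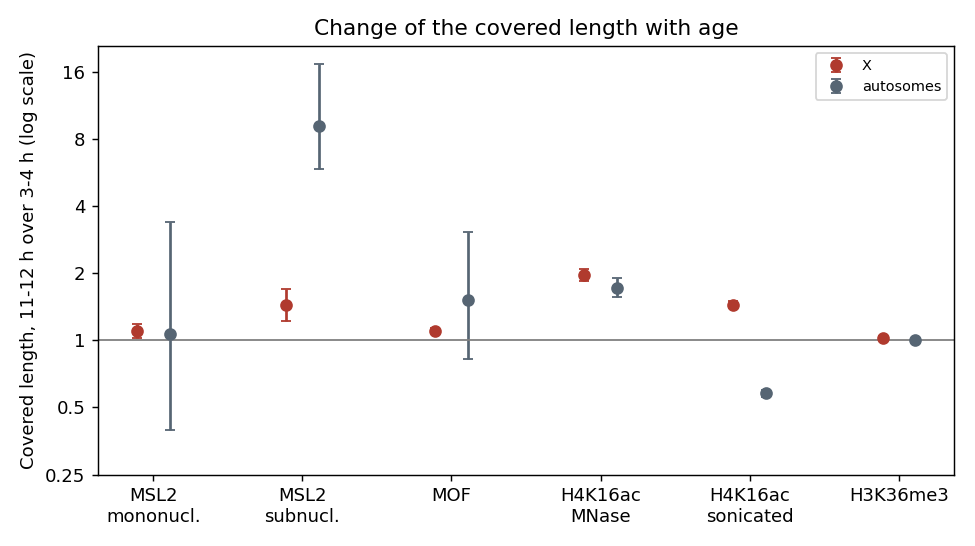
Covered length at 11-12 h over that at 3-4 h on a log axis, for the X (red) and the autosomes (grey), with 95% intervals from a bootstrap of 1-Mb blocks. Sonicated H4K16ac lies above 1 on the X (1.45) and below 1 on the autosomes (0.578).

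Region width was compared to ask whether the marked stretches lengthened. H4K16ac regions on the X became wider: the median went from 3143 to 4852 bp on MNase chromatin (permutation test, adjusted p = 5e-05) and from 2958 to 3773 bp on sonicated chromatin (adjusted p = 0.000533). The widest of them, over mip130, a subunit of a chromatin complex with Myb, reached 79.0 kb on MNase chromatin at 11-12 h (X 1851754 to 1930788) and touched 24 protein-coding genes. Autosomal H4K16ac regions became narrower on sonicated chromatin, 2010 to 1757 bp (permutation test, adjusted p = 5e-05), and wider on MNase chromatin, 1264 to 1417 bp (adjusted p = 0.03). MSL2 mononucleosomal regions on the X went from 4240 to 3824 bp (permutation test, adjusted p = 0.026) and autosomal H3K36me3 regions from 3922 to 3776 bp (adjusted p = 0.0105); both calls ended when regions within 1 kb were joined, at -435.5 and -120.5 bp. MOF regions on the X had medians of 5531 and 5420 bp (permutation test, adjusted p = 0.74). These are two-sided permutation tests of medians with 100000 resamples, adjusted over 10 comparisons, in which 1e-05 is the smallest raw p they can give. MSL2 subnucleosomal peaks were all 200 bp wide and were not compared.

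The next question was how much of the pattern of 3-4 h was present at 11-12 h. X-linked regions of 5 lists were largely kept: 213 of 238 MSL2 mononucleosomal regions (89.5%), 459 of 475 MOF regions (96.6%), 854 of 863 MNase H4K16ac regions (99.0%), 772 of 803 sonicated H4K16ac regions (96.1%) and 678 of 712 H3K36me3 regions (95.2%) overlapped a region of 11-12 h. MSL2 subnucleosomal peaks were kept least among X-linked lists, 80 of 116 (69.0%), with 5 of 14 (35.7%) on the autosomes. Autosomal regions were kept less often for MOF, 8 of 40 (20.0%), MNase H4K16ac, 399 of 646 (61.8%), and sonicated H4K16ac, 1167 of 2043 (57.1%), but not for H3K36me3, 2869 of 3003 (95.5%). The widest sonicated H4K16ac regions on the X present at both stages lay over mip130, the clock gene per, pcx, e(y)3, HERC2, mxc, Dlic and nonC, and those on MNase chromatin over mip130, the dynamin gene shi, c11.1, sd, mmd, C3G, Nadsyn and Set2, which encodes the H3K36 methyltransferase. Widest among sonicated regions listed at 11-12 h only were C3G (11.4 kb, X 6781386 to 6792826), CG7536, Ptp4E, CG1677, the receptor gene N (8.09 kb), GCS2alpha, CG43658 and Trf2. On MNase chromatin these were Tpst (30.6 kb, X 13574459 to 13605016), Rala, CanA-14F, Ptp4E, the sex-determination gene Sxl (15.1 kb, X 7075527 to 7090608), NFAT, CG43155 and ctp. Regions of 3-4 h only were narrow, such as those over SdhBL (2.04 kb), CR33221, mnb, Ankle2, Ca-alpha1T, CG32767, lncRNA:CR45668 and zld on sonicated chromatin. Their MNase counterparts lay over yl, the yolk protein receptor (5.71 kb), peb at 2 places, per, Mct1, fs(1)h, cyr and CG11122. For H3K36me3 the widest shared regions lay over HUWE1 (19.7 kb), pcx, lva, e(y)3, pcm, tay, east and Nup205. CHES-1-like (5.73 kb), Socs16D, Hr4, Mnt, shi, csw, hiw and tw had regions of 11-12 h only. The widest H3K36me3 region of 3-4 h only covered 5.88 kb of zld (X 19776576 to 19782454), the activator of the early zygotic genome, followed by CG14200, CG7884, Rala, N, CG2865, CG12994 and fog. The difference between X and autosomes in the share kept was 76.6 points for MOF (61.7 to 86.2, adjusted p = 3.13e-31), 37.2 for MNase H4K16ac (33.4 to 41.0, adjusted p = 4.25e-91), 39.0 for sonicated H4K16ac (36.4 to 41.5, adjusted p = 2.33e-111) 33.3 for MSL2 subnucleosomal peaks (6.22 to 54.1, adjusted p = 0.0222) and -0.313 for H3K36me3 (-2.26 to 1.25, adjusted p = 0.689), by Fisher's exact test. In the other direction, sonicated H4K16ac regions of 11-12 h were found at 3-4 h less often on the X, 63.3%, than on the autosomes, 84.1% (-20.7 points, exact test, adjusted p = 1.17e-28). MNase H4K16ac had the larger share on the X, 48.0% against 39.5% on the autosomes (8.50 points, exact test, adjusted p = 0.000399), and so did MOF, 84.2% against 8.54% (75.7 points, exact test, adjusted p = 6.24e-42); the MOF call ended in the widest 50% of each list (82.9 points, exact test, adjusted p = 0.29). Overlap was above that of circular shifts along each arm in each of the 24 comparisons (permutation of positions, adjusted p from 0.00016 to 0.0013, one-sided, with 0.0001 the smallest raw p the shifts can give). The differences between X and autosomes above were tested against 0, although shifted MOF and H4K16ac regions overlapped far more on the X, where these lists are denser. For regions of 3-4 h the shifted share was 39.65% on the X and 2.94% on the autosomes for MNase H4K16ac, 30.6% and 4.89% for sonicated H4K16ac, and 24.6% and 0.339% for MOF. For regions of 11-12 h it was 28.3% and 1.89% for MNase H4K16ac. Overlap was thus 2.50 times the shifted share on the X and 21.0 times on the autosomes for MNase regions of 3-4 h, 3.14 and 11.7 times for sonicated regions and 3.93 and 59.1 times for MOF, so the higher share on the X does not by itself show that its regions were better kept. MSL2 mononucleosomal regions had only 7 and 8 autosomal members, so their X-autosome difference, 60.9 points by Fisher's exact test (adjusted p = 0.00053), rested on few regions.

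Overlap between the lists asked whether the complex, its enzyme and its product lay together. MSL2 mononucleosomal regions on the X carried MOF at nearly every site, 236 of 238 (99.2%) and 307 of 310 (99.0%). MOF was wider spread than MSL2: 42.3% of X-linked MOF regions held an MSL2 mononucleosomal region at 3-4 h and 46.8% at 11-12 h (exact test, adjusted p = 0.231). MSL2 subnucleosomal peaks on the X overlapped MSL2 mononucleosomal regions in 104 of 116 cases (89.7%) at 3-4 h and in 95 of 167 (56.9%) at 11-12 h, and MOF in 112 (96.6%) and 115 (68.9%). Of X-linked MOF regions, 92.8% and 98.7% held sonicated H4K16ac, and the share of sonicated H4K16ac regions with MOF fell from 72.4% to 57.0%. H3K36me3 regions with sonicated H4K16ac rose from 87.8% to 97.6% on the X and fell from 59.2% to 41.1% on the autosomes, whereas with MNase H4K16ac the autosomal share rose from 19.6% to 27.3%. None of the 128 autosomal MSL2 subnucleosomal peaks of 11-12 h overlapped MOF (0%, interval up to 2.91%), 2 overlapped an MSL2 mononucleosomal region, 3 sonicated H4K16ac and 13 H3K36me3. By Fisher's exact test between stages, adjusted over 30 pairs, the change for subnucleosomal peaks was -32.8 points with MSL2 mononucleosomal regions (-41.5 to -22.8, adjusted p = 2.94e-09) and -27.7 points with MOF (-35.4 to -19.4, adjusted p = 2.16e-09). The change for H3K36me3 with sonicated H4K16ac by that exact test was 9.77 points on the X (adjusted p = 3.26e-13) and -18.1 points on the autosomes (adjusted p = 6.95e-45). Both were tested against 0, although the shifted share moved in the same directions. It went from 23.8% to 30.7% on the X and from 11.1% to 7.23% on the autosomes. The rise of MOF regions with sonicated H4K16ac (5.83 points, exact test, adjusted p = 6.25e-06) went to 3.06 points in the widest 50% of each list, no longer past the threshold (adjusted p = 0.0862).

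The genes of the roX RNAs, the noncoding RNAs of the complex, were examined as members of the fixed list of complex genes. At roX2 (X 11579065 to 11580432) an MSL2 mononucleosomal region of 4.29 kb (X 11578013 to 11582297) and a subnucleosomal peak (X 11580160 to 11580359) were listed at 3-4 h, and neither list of 11-12 h had a region over the gene, although an MSL2 mononucleosomal region of 11-12 h lay just past its end (X 11580907 to 11584976). MOF covered roX2 at both stages, in a region of 13.0 kb at 3-4 h and of 24.4 kb at 11-12 h. The longer region took in Polr2A, the largest subunit of RNA polymerase II, which at 3-4 h already had a separate MOF region (X 11562013 to 11569804). The MNase H4K16ac region over roX2 spanned 8.64 kb at 3-4 h, with other regions next to it, and 41.2 kb at 11-12 h. Over roX1 (X 3857230 to 3862697) no MSL2 mononucleosomal region was listed, and a subnucleosomal peak was listed at 11-12 h only (X 3861252 to 3861451). MSL2 mononucleosomal regions lay over mof, arm, Polr2A, wapl, RpL22 and elav at both stages. Of 384 X loci with any MSL2 region, 68 were in all 4 MSL2 lists, the widest over dlg1 (15.5 kb, X 11393951 to 11409434), PhKgamma, pcx, Tao, CG34408 and slpr. These are descriptions of single sites in lists with no score, so a region missing from a list is not a measured absence of the protein.

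**Figure D3:**
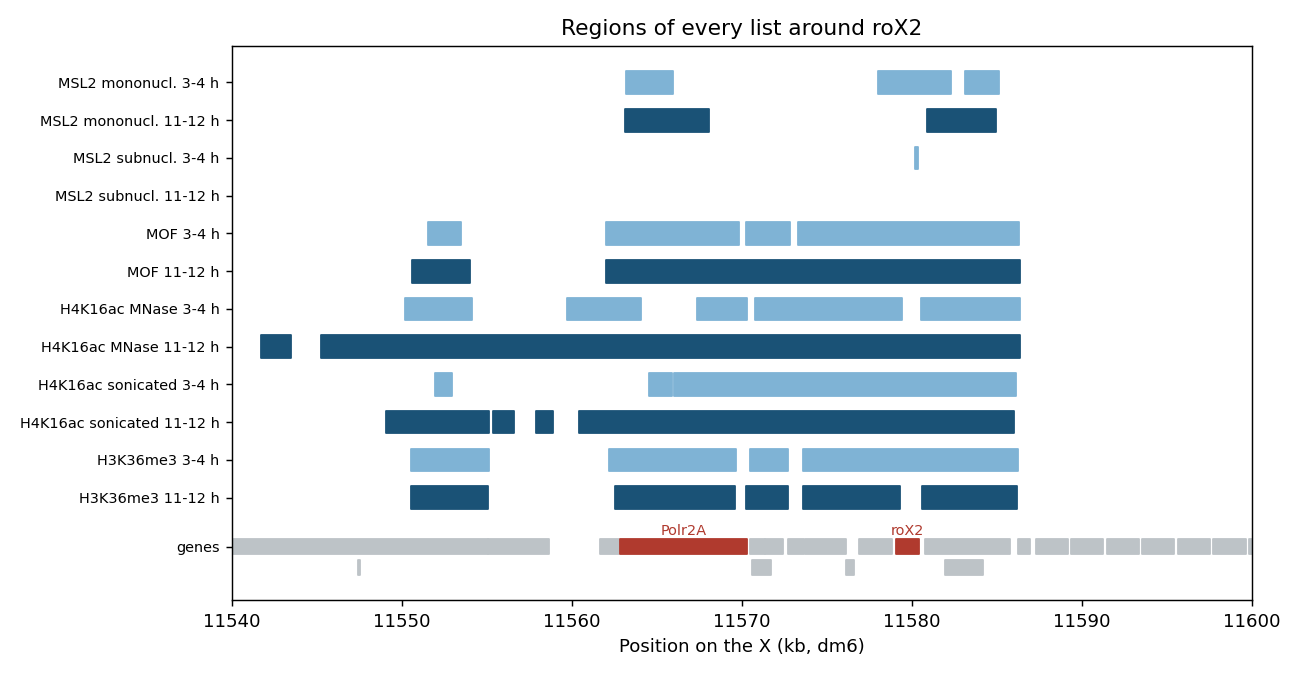
Regions of each list around roX2 on the X, in kb on dm6, at 3-4 h (light) and 11-12 h (dark), with gene bodies below and roX2 and Polr2A in red. The MNase H4K16ac region over roX2 spans 8.64 kb at 3-4 h and 41.2 kb at 11-12 h.

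The share of protein-coding genes touched by each list was compared between the stages. On the X, genes with sonicated H4K16ac rose from 1301 to 1496 of 2197 (59.2% to 68.1%), with 207 gained and 12 lost, and genes with MNase H4K16ac rose from 1299 to 1636 (59.1% to 74.5%), with 338 gained and 1 lost. X genes with MOF rose from 1066 to 1201 and X genes with MSL2 mononucleosomal regions from 391 to 453. Autosomal genes with sonicated H4K16ac fell from 3832 to 2545 of 11645 (32.9% to 21.9%), with 273 gained and 1560 lost, whereas those with MNase H4K16ac rose from 1049 to 1653. Autosomal genes with an MSL2 subnucleosomal peak rose from 5 to 88 and with MOF from 46 to 142. Genes with H3K36me3 numbered 1182 and 1219 on the X (exact test, adjusted p = 0.3) and 5911 and 5996 on the autosomes (adjusted p = 0.3). By Fisher's exact test the changes on the X were 8.88 points for sonicated H4K16ac (6.04 to 11.7, adjusted p = 2.26e-09), 15.3 for MNase H4K16ac (12.6 to 18.1, adjusted p = 1.39e-26), 6.15 for MOF (3.19 to 9.08, adjusted p = 8.92e-05) and 2.82 for MSL2 (0.492 to 5.15, adjusted p = 0.0259). On the autosomes, sonicated H4K16ac changed by -11.1 points (-12.2 to -9.91, exact test, adjusted p = 5.59e-79). These tests treat the genes of the 2 stages as independent. With the widest 50% of each list, the MSL2 change on the X was no longer past the threshold (1.82 points, exact test, adjusted p = 0.0978) and the autosomal MOF change turned to -0.0515 points (adjusted p = 0.0521).

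The title of the series names gene arrangement on the X, so H4K16ac was set against the distance to MSL2 sites, taken as the subnucleosomal peaks of 11-12 h. Of these 167 X-linked peaks, 95 overlapped an MSL2 mononucleosomal region and 52 neither such a region nor MOF, so some may not be MSL2 sites. X genes near a site carried H4K16ac most often at both stages. Of the genes within 5 kb, 81.2% had sonicated H4K16ac at 3-4 h and 89.0% at 11-12 h. From 5 to 20 kb these shares were 71.0% and 81.8%, from 20 to 50 kb 54.5% and 63.8%, and beyond 50 kb 41.3% and 49.2%. On MNase chromatin genes within 5 kb went from 81.9% to 93.6%, those from 5 to 20 kb from 71.4% to 89.4%, and those beyond 50 kb from 41.3% to 55.7%. H3K36me3 declined with distance as well, from 70.3% within 5 kb to 40.9% beyond 50 kb at 3-4 h and from 73.2% to 41.1% at 11-12 h. The median distance of X genes with sonicated H4K16ac was 15.8 kb at 3-4 h, against 47.0 kb for genes without it (-31.1 kb), and 17.0 kb against 53.1 kb at 11-12 h (-36.2 kb). Each of the 6 gene comparisons had p = 1e-05, the smallest that 100000 permutations can give, two-sided. Regions on the X listed only at 11-12 h lay farther from the sites than regions listed at both stages, at a median of 28.0 against 18.8 kb for sonicated H4K16ac (permutation test, adjusted p = 0.00437), 26.2 against 14.6 kb for MNase H4K16ac (adjusted p = 0.00036) and 36 against 20.2 kb for H3K36me3 (adjusted p = 0.0288). Measured between midpoints, these 3 differences were no longer past the threshold (7.43 kb, 4.93 kb and 16.6 kb, permutation test, adjusted p = 0.0855, 0.222 and 0.0711). That for H3K36me3 also ended with the subnucleosomal peaks of 3-4 h as sites (9.66 kb, permutation test, adjusted p = 0.285). Genes close together share their distances, so they are not independent in these tests. With MSL2 mononucleosomal regions of 11-12 h as sites instead, the decline was steeper. Sonicated H4K16ac then lay on 89.9% of genes within 5 kb and 13.1% beyond 50 kb at 3-4 h, and on 96.0% and 18.2% at 11-12 h. H3K36me3 went from 81.5% to 12.9% over the same distances at 3-4 h.

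**Figure D4:**
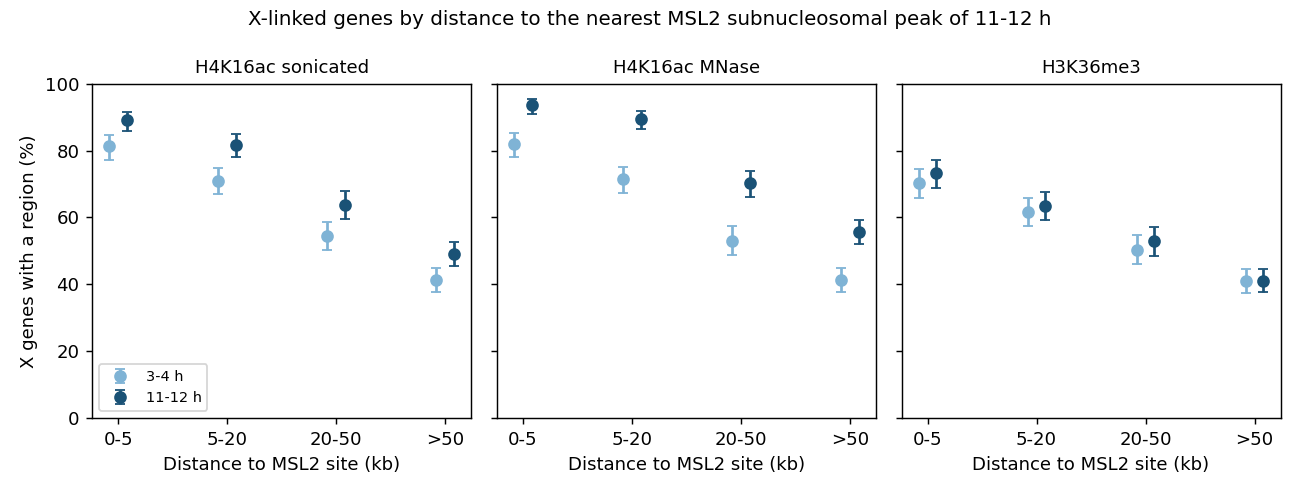
Share of X-linked protein-coding genes with a region, in percent with Wilson 95% intervals, by distance in kb to the nearest MSL2 subnucleosomal peak of 11-12 h, at 3-4 h (light) and 11-12 h (dark). For sonicated H4K16ac at 3-4 h the share goes from 81.2% within 5 kb to 41.3% beyond 50 kb.

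Placement in genes was compared by region midpoint. Most midpoints of X-linked regions lay in gene bodies: 97.1% at both stages for MSL2 mononucleosomal regions, 96.0% and 95.2% for MOF, and 97.9% and 97.4% for H3K36me3, against 74.6% of the length of the X. MNase H4K16ac midpoints on the X in gene bodies fell from 95.4% to 89.4%, and sonicated H4K16ac midpoints on the autosomes rose from 76.0% to 81.1%, where genes take up 68.4% of the length. By Fisher's exact test, adjusted over 12 comparisons, these changes were -5.92 points (-8.49 to -3.42, adjusted p = 4.29e-05) and 5.16 points (2.38 to 7.88, adjusted p = 0.00198). Neither of the other X changes for H4K16ac and H3K36me3 passed, and MSL2 subnucleosomal peaks on the X, 89.7% and 80.8%, had an adjusted p of 0.187. The autosomal change turned to -0.0442 points when any base of a region in a gene counted (exact test, adjusted p = 1).

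Gene lists fixed before the data were examined were compared with the other protein-coding genes of the same chromosome class. Ribosomal protein genes on the autosomes carried sonicated H4K16ac and H3K36me3 far more often than other genes: sonicated H4K16ac lay on 65 of 77 (84.4%) at 3-4 h and 61 of 77 (79.2%) at 11-12 h, among them RpL40, RpL37A and RpS15Ab. MNase H4K16ac lay on 12 of 77 at 3-4 h (15.6% against 8.96% of other genes, exact test, adjusted p = 0.291) and on 48 of 77 at 11-12 h, as at RpL36A and RpL38, and H3K36me3 on 72 and 71. On the X, 14 of 14 ribosomal protein genes, such as RpL22, RpS6 and RpS5a, had H3K36me3 at both stages, and so had 10 of 10 X housekeeping genes, such as Act5C, Polr2A and wapl. Early patterning genes were free of H4K16ac in all 4 of its lists, on 0 of 4 X members and 0 of 19 autosomal members, and H3K36me3 lay on the bodies of hb, Kr, h and odd at 3-4 h, 4 of 19, and on 0 of 19 at 11-12 h. Hox genes, from lab to Abd-B, had neither mark at either stage, 0 of 8. Of the autosomal genes for the MSL complex, 5 of 5 (msl-1, msl-2, msl-3, mle and Clamp) had sonicated H4K16ac at 3-4 h, and 3 of 5 at 11-12 h, without msl-3 and Clamp. The list of X counting and sex determination, called X-counting genes below, had 6 members on the X. MNase H4K16ac lay on 0 of 6 at 3-4 h and on 3 of 6, sisA, Sxl and snf, at 11-12 h. Sonicated H4K16ac lay on 2 of 6, Sxl and snf, already at 3-4 h and on the same 3 at 11-12 h. Neural genes on the X had MNase H4K16ac on 2 of 6 at 3-4 h, elav and Fas2, and on 5 of 6 at 11-12 h, with cac, para and Sh added. Other X genes had it in 59.2% and 74.4%, and neither comparison passed the threshold. Sonicated H4K16ac lay on 3 of 6 neural genes at 3-4 h and 5 of 6 at 11-12 h. The X-linked muscle genes up and wupA, for troponin subunits, had 0% and 1.8% of their bodies in MNase H4K16ac at 3-4 h and 100% and 87% at 11-12 h, but 0% and 8.8% in sonicated H4K16ac at 11-12 h, and MNase H4K16ac lay on 0 and then 1 of 8 autosomal muscle genes. Germ cell genes had H3K36me3 on 6 of 8 at both stages, such as nos, vas and piwi, against 50.7% and 51.5% of other autosomal genes (exact test, adjusted p = 0.751 at both). By Fisher's exact test, adjusted over 168 tests of 9 gene lists against 12 region lists, of which 16 passed, the adjusted p for autosomal ribosomal protein genes was 5.83e-19 and 1.52e-24 for sonicated H4K16ac and 1.80e-20 for MNase H4K16ac at 11-12 h. It was 0.0044 and 0.00979 for H3K36me3 on X-linked ribosomal protein genes, 0.0155 for early patterning genes in sonicated H4K16ac at 3-4 h, and 2.96e-05 for their H3K36me3 at 11-12 h. Calls near the threshold by the same exact test were the MSL complex (adjusted p = 0.0462), X-counting genes (0.0485), early patterning genes on the X in MNase H4K16ac at 11-12 h (0.0472), Hox genes for H3K36me3 (0.0446 and 0.0428) and X housekeeping genes (0.0408 and 0.0428). Each of these, apart from early patterning genes, ended under the 3 alternative ways to count a gene. The H4K16ac calls of early patterning genes on the X and the autosomes ended with 50% of the gene body or the widest 50% of each list required. Changes between the stages within a list were not tested, and gene length and expression were not matched. With the widest 50% of each list, 6 of 140 tests passed, and the call for ribosomal protein genes ended for H3K36me3 on the X (-4.55 points at 3-4 h, 7.77 at 11-12 h) and for autosomal MNase H4K16ac at 11-12 h (3.97 points).

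H4K16ac was measured on both preparations, which asked whether its stage change depended on the chromatin. Sonicated regions on the 5 arms went from 2846 to 2306, and MNase regions from 1509 to 1830. The autosomes carried this difference: sonicated regions went from 2043 to 1425 and MNase regions from 646 to 996, while on the X they went from 803 to 881 and from 863 to 834. Of autosomal sonicated regions, 26.9% at 3-4 h and 49.8% at 11-12 h overlapped an MNase region of the same stage. In the other direction, autosomal MNase regions with a sonicated region fell from 86.2% to 70.2%. These shares move with the lengths of the lists, so neither shows by itself that the preparations came closer or drew apart. By Fisher's exact test the log2 odds ratio of stage by preparation was 0.58 over all regions (p = 1.69e-19) and 1.14 on the autosomes (p = 3.19e-39), and it turned to -0.18 on the X (p = 0.0683).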

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

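Chosen only after the results were seen were the tests of calling depth, of dilution, of MOF at autosomal MSL2 peaks, of wider calling and of gene ends between X and autosomes, the split of the preparation comparison by chromosome, and the permutation of MSL2 fragment class. The deposited lists hold no value per sample, so no sample was tested for standing apart from its group.

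The change of H4K16ac with age differed between the preparations, with a log2 odds ratio of 0.58 over all regions and 1.14 on the autosomes, where sonicated regions fell from 2043 to 1425 and MNase regions rose from 646 to 996. A shallower sonicated list at 11-12 h as the only change is argued against, since the same list covered 1.45 times as much of the X (1.40 to 1.49). Beside a gain on the X, a lower depth stays open for the autosomal fall, since such a gain can hide it on the X. Dilution of autosomal signal by the gain on the X stays open: the autosomal region number rose 1.54 times (1.42 to 1.68) on MNase chromatin, but that rise is part of the pattern and comes from another preparation. A loss at these places that both preparations see stays open too. The 876 autosomal sonicated regions of 3-4 h only were in the MNase list of 11-12 h more often (194) than in that of 3-4 h (147), by 5.37 points (1.66 to 9.06). That interval ignores that the same regions were looked up in both lists, 78 found at 3-4 h only and 125 at 11-12 h only. The rise is 1.32 times as many in a list 1.54 times as long, so the length of the list alone can give it. Also open, and untested, are the MNase digestion, at 0.9 and 2.9 units per g, the unknown calling of the lists, and a real difference of stage that only 1 preparation shows. The preparations differ as well in their replicates, A and B when sonicated and D to F with MNase, and in fragment selection, which was not tested either.

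MSL2 subnucleosomal peaks differed from mononucleosomal regions in the change of their X share, by -33.0 points (permutation p = 1e-05, the smallest the permutations can give), since 128 autosomal peaks appear at 11-12 h. MOF regions overlapped 0 of 128 of these peaks on the autosomes and 115 of 167 on the X (-68.9 points, -75.4 to -60.9). The MOF list is mononucleosomal, however, and MSL2 mononucleosomal regions likewise overlapped only 2 of the 128. On the X, MSL2 mononucleosomal regions overlapped 95 of the 167 peaks, fewer than MOF, so the MOF list can reach peaks outside them. Sonicated H4K16ac, whose list is not named by fragment size, overlapped 3 of the 128 autosomal peaks (2.34%, shifted 2.53%). It overlapped 112 of the 167 on the X (67.1%, shifted 23.4%). These values argue against an MSL complex that acetylates H4K16 at most of the autosomal peaks. MOF or acetylation below the detection of these lists stays open. A background of equal density on every arm stays open: X peaks with neither MSL2 mononucleosomal regions nor MOF occur 1.88 times as densely (1.33 to 2.61) as autosomal peaks, but MSL2 sites below the detection of those lists can add to the X peaks, so the excess does not count against it as planned. Of the autosomal peaks, 46.9% (38.5 to 55.5) lie within 500 bp of a gene end, against 18.25% for shifted positions (shift permutation p = 0.0001, the smallest the shifts can give). Open chromatin at gene ends needs such a value. X-linked peaks of the list share it, at 35.3% against 16.2% (shift permutation p = 0.0001), and the difference of 11.55 points did not pass (exact test, adjusted p = 0.0995). The MOF, H4K16ac and H3K36me3 lists of 11-12 h also exceeded their shifted share, such as H3K36me3 on the X (30.0% against 16.2%). The excess therefore does not single out open chromatin, which was not measured. H3K36me3 lay at 10.2% of the autosomal peaks, against 13.65% when shifted. MSL2 without MOF at such sites and a stage difference in MNase digestion stay open, and neither was tested.

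H4K16ac covered more of the X at 11-12 h in both preparations, which a biologist may read as spreading or as a change of calling. Wider calling of every region as the only change is argued against on sonicated chromatin, where the median width of autosomal regions changed by -253 bp (permutation p = 1e-05). Autosomal regions also fell in number there for a cause left open above, so wider calling beside a weaker autosomal signal stays open. On MNase chromatin wider calling stays open by itself too, since autosomal regions widened there by 152.5 bp (permutation p = 0.018), less than the 1708 bp on the X. Growth from the regions of 3-4 h had the values it needs: 75.7% of the 1.82 Mb gained on sonicated chromatin lay within 5 kb of a region of 3-4 h, against 30.0% for shifted regions (shift permutation p = 0.001), and 64.0% against 31.0% on MNase chromatin (p = 0.001). Any widening of a kept region adds gained length beside it, and the shifts break that link. The test therefore cannot tell growth from wider calling. Nearness to MSL2 sites also had the values it needs, with a median of 12.6 kb from sonicated regions of 11-12 h only to MSL2 mononucleosomal regions, against 32.6 kb for shifted regions (shift permutation p = 0.003), and 17.3 against 32.5 kb on MNase chromatin (p = 0.003). Regions listed at both stages lay nearer still, at 1.01 kb on sonicated and 0 kb on MNase chromatin (permutation test, adjusted p = 3e-05 for each). These distances run between edges, which favours wide regions, and midpoint distances to these sites were not computed. H3K36me3 regions of 11-12 h only lay at a like distance from these sites, 12.4 kb, so that distance is not particular to H4K16ac. Clustering of active genes was not tested and the shifts do not keep it, so growth, nearness to MSL2, gene density and wider calling may each account for part of the pattern, and the stage itself stays untested.

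Chromosome 4 enters no test except that of the X share over every sequence of a list, and its lists were above the 3 regions that a count of 0 allows: sonicated H4K16ac had 38 regions at 3-4 h and 29 at 11-12 h, MNase H4K16ac 11 and 33, and H3K36me3 56 and 59. MOF had 5 regions on the Y chromosome at 11-12 h, above the same limit.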

How the results depend on the processing

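The same number of widest regions for the X share, the settings of the preparation comparison and the width classes for gene ends, which changed no call, were chosen only after the data were seen. No alternative changed the direction or the side of the threshold of stage overlap (92 values), of overlap between lists at one stage (240) or of X gene distance (18), and 85 values of overlap between stages, 23 of X share, 21 of region distance, 30 of genes touched and 418 of fixed lists held as well. Where a value below changed, the cause was not tested, except that the widest 50% keeps fewer regions; values are 11-12 h minus 3-4 h unless stated, with adjusted p. In the widest 50% of each list, the X share of MOF reversed to 1.22 points (0.309), and MOF genes on the autosomes reversed to -0.0515 points (0.0521). MSL2 mononucleosomal genes on the X fell short at 1.82 points (0.0978), MOF with sonicated H4K16ac at 3.06 (0.0862) and sonicated H4K16ac with H3K36me3 on the X at -5.39 (0.142). There the X minus autosome difference in regions of 11-12 h found at 3-4 h was 66.7 points for MSL2 mononucleosomal regions (0.422) and 82.9 for MOF (0.29). With the same number of widest regions the X share of MOF changed by -0.0303 points (1). Counted as length, the X share changed by -0.881 points for MOF and 22.05 for sonicated H4K16ac, and reversed to 2.10 for MNase H4K16ac. With regions joined, median width changed by -435.5 bp for MSL2 mononucleosomal regions on the X (0.106) and by -120.5 bp for autosomal H3K36me3 (0.5). With overlap of 50% of the shorter region, passing changes were 6.60 points for MSL2 mononucleosomal regions with sonicated H4K16ac (0.000133), 5.18 with H3K36me3 (0.0222) and 21.3 for autosomal MOF with sonicated H4K16ac (0.0476). With midpoint distance, regions of 11-12 h only minus both gave 7.43 kb for sonicated H4K16ac (0.0855), 4.93 for MNase H4K16ac (0.222) and 16.6 for H3K36me3 (0.0711), and with subnucleosomal peaks of 3-4 h 9.66 kb for H3K36me3 (0.285). With MSL2 mononucleosomal regions as sites, regions of 3-4 h only minus both passed at 8.82 kb for sonicated H4K16ac (0.00146) and 11.2 kb for H3K36me3 (9e-05). With any base in a gene, autosomal H4K16ac changed by -1.25 points on MNase chromatin (0.044) and reversed to -0.0442 on sonicated chromatin (1). The preparation comparison reversed to -0.18 on the X (0.0683).

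For the fixed lists, 16 of 168 tests passed, with 11, 13 and 6 under the 3 alternatives, and values are members minus other genes in points. With at least 50% of the gene body, no longer passing were MSL complex genes in sonicated H4K16ac at 3-4 h (46.2), X-counting genes (-47.7) and X early patterning genes (-66.3) in MNase H4K16ac at 3-4 h and 11-12 h, autosomal early patterning genes in sonicated H4K16ac at 3-4 h (-13.9), and in H3K36me3 at the 2 stages Hox genes (-37.06 and -37.05) and X housekeeping genes (11.0 and 10.5). Newly passing were X ribosomal protein genes in sonicated H4K16ac (48.4 and 44.5) and MNase H4K16ac at 11-12 h (34.0). With 1 kb added, the calls that ended were the MSL complex (60.8), X-counting (-48.0), Hox (-45.2 and -45.8) and X housekeeping (39.3 and 37.5). Early patterning genes on the autosomes newly passed in sonicated H4K16ac at 11-12 h (-28.0) and H3K36me3 at 3-4 h (-36.7), and autosomal ribosomal protein genes in MNase H4K16ac at 3-4 h (17.3). With the widest 50%, calls ended for the MSL complex (41.6), X-counting (-52.4), early patterning on the X (-72.6) and the autosomes (-18.5), Hox (-32.67 and -32.5), X housekeeping (27.0 and 35.0), X ribosomal protein genes in H3K36me3 at 11-12 h (7.77; reversed to -4.55 at 3-4 h) and autosomal ones in MNase H4K16ac at 11-12 h (3.97). Early patterning genes passed there in H3K36me3 at 3-4 h (-32.7).

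No paired analysis was possible because each list pools the replicates of a group. For the same reason the replicate block and lists without a replicate were not run, nor were the GA repeat and promoter settings, which need a genome sequence or strand. MSL2 subnucleosomal peaks share 1 width, so they have no widest 50% and no test of 50% of a gene body, and in overlaps they were used whole while the other list was cut. For overlap with the other stage or another list, the widest 50% was taken on the X and on the autosomes apart. For the X share, genes and the X minus autosome difference it was taken from the whole list, and there MSL2 mononucleosomal regions of 3-4 h had no autosomal region left for the X minus autosome difference. Depth is unknown, so a region missing from a list cannot be told from 1 below its detection.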

Other observations

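All tests in this part were chosen after the results of the report were seen, and the genes named were chosen after their values were seen. H4K16ac sat differently in genes on the X and on the autosomes. Of autosomal sonicated H4K16ac regions, 86.4% had their midpoint within 500 bp of a gene end at 3-4 h and 84.8% at 11-12 h, against 35.0% and 26.2% on the X (Fisher's exact test, adjusted over 24 tests, p = 2.07e-156 and 7.28e-180). MNase H4K16ac showed the same direction, with 59.6% and 67.6% on the autosomes and 25.5% and 24.7% on the X (exact test, adjusted p = 2.51e-40 and 3.74e-76). Regions on the X are wider, but among regions of 1 to 2 kb the shares for sonicated H4K16ac were still 81.4% and 82.4% on the autosomes and 24.5% and 22.1% on the X (exact test, adjusted over 8 tests, p = 1.03e-66 and 2.28e-73), and those for MNase H4K16ac 57.7% and 65.4% against 22.4% and 18.4% (adjusted p = 3.92e-22 and 3.20e-38). Among the widest autosomal sonicated regions found at both stages were those over PPO3, CG31549, msl-1, which encodes a scaffold of the dosage compensation complex, the tubulin gene alphaTub84B, CG30414, Rap2l and Tap42. Those of 3-4 h only lay over CG6785, Ibf1, CG7069, koko, asRNA:CR44179, Mapmodulin, Tif-IA and eIF2A. The 1167 kept regions had a median width of 2270 bp, 90.9% held H3K36me3 and 90.2% lay at a gene end; the 876 not listed at 11-12 h had 1756 bp, 80.9% and 81.3% (difference of medians 513.5 bp, permutation p = 1e-05, the smallest it can give).

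The few autosomal MOF regions lay at different places in the lists of the 2 stages. At 3-4 h 11 of 40 lay at a gene end (27.5%), and the 10 widest lay over Alh, Bruce, which encodes an inhibitor of apoptosis, the cell cycle gene E2f1, CG1965, ear, AGO1, which encodes an Argonaute protein, GCC88 and syd. At 11-12 h 66 of 82 lay at a gene end (80.5%), a difference of 53.0 points (34.8 to 66.4, exact test, adjusted p = 8.41e-08), as at CG7183 and Tap42; X-linked MOF regions at gene ends went from 25.7% to 34.2% (exact test, adjusted p = 0.00901). A cluster more than 100 kb from any gene in the table lay near the start of 3R, with 4 autosomal MOF regions at 3-4 h and 9 at 11-12 h, from 86527 to 122814. Most of the 10 widest autosomal MOF regions of 11-12 h lay in this cluster. On the Y, MOF had 2 regions at 3-4 h and 5 at 11-12 h (1417726 to 1457056), also more than 100 kb from any gene. MSL2 mononucleosomal regions on the autosomes lay at lncRNA:Hsromega, a heat shock RNA gene, ed, tRNA:iMet-CAT-1-1, hid, Sema1a, Alh and CG1142 at 3-4 h. At 11-12 h they lay at Mob2, tRNA:iMet-CAT-1-1, Roc2, Pu, CG1142, CG6006 and CG14326 and near CG43149.

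H4K16ac lay mostly on genes with H3K36me3 on both chromosome classes, and on sonicated chromatin its share among them rose on the X and fell on the autosomes. Of the 1265 X genes with H3K36me3 at either stage, 89.3% had sonicated H4K16ac at 3-4 h and 98.2% at 11-12 h (8.85 points, 7.03 to 10.8, exact test, adjusted p = 2.02e-21), and of the 932 without it 18.4% and 27.3%. MNase H4K16ac on those 932 genes went from 17.8% to 40.9%, by 23.1 points (19.0 to 27.0, exact test, adjusted p = 8.01e-28). Of the 6242 autosomal genes with H3K36me3, 57.7% had sonicated H4K16ac at 3-4 h and 39.2% at 11-12 h (-18.4 points, -20.2 to -16.7, exact test, adjusted p = 7.16e-94), while MNase H4K16ac went from 15.96% to 25.1%. On chromosome 4, where stage changes were not tested, of 80 protein-coding genes, 46 had sonicated H4K16ac at 3-4 h and 31 at 11-12 h, 11 and 31 had MNase H4K16ac, and 49 and 53 had H3K36me3. MOF and MSL2 mononucleosomal regions were listed on none of these 80 genes at either stage.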
